A study of Homo sapiens with 8 samples.

How the data were processed

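Poly(A) RNA from HEK293T cells was reverse transcribed with random hexamers and sequenced as read pairs on an Illumina NovaSeq, per the labels' protocols. The 8 libraries comprise WT and the sgKDM5C, sgKDM6A and sgKMT2B knockouts, with 2 libraries in each of the 4 groups, and each library's group and replicate number were taken from its label. The authors deposited a table of raw read counts per Ensembl gene, 1 column for each library, which they made with STAR (version not given in the sources used here) and HTSeq 0.11.2 on GRCh38 (hg38), per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense neighbour cannot be told apart, and genes with near-identical copies can lose or gain reads, so such genes are uncertain, and only the clearest cases are pointed out where they are named.

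The table held 60617 gene identifiers. Of these, 60261 had a symbol in a table of gene names, 58542 were in the GENCODE v29 annotation of GRCh38, which gave chromosomes, coordinates and biotypes, and 60596 had a symbol from either source. No value in the table was changed before testing. Total counts ran from 15868353 in WT replicate 2 to 27591724 in sgKDM6A replicate 2, so that 3 counts in a library corresponded to 0.189 and 0.109 CPM. Genes of the mitochondrial genome had 0 counts in every library. Between 97.66% and 98% of the counts were in protein-coding genes, and the 20 most abundant genes took 8.77% to 10.33%. Replicates of each group differed by more than sampling noise, with chi-square values per degree of freedom of 16.91 in WT, 11.12 in sgKDM5C, 9.82 in sgKDM6A and 8.21 in sgKMT2B, and each library was counted as 1 replicate.

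Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood functions glmQLFit and glmQLFTest on all 8 libraries with 1 coefficient per group, which leaves 4 residual degrees of freedom per gene for a shared estimate of the spread. Library sizes were scaled with TMM factors, which lay between 0.965 and 1.056, and filterByExpr by group left 17527 genes. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Each knockout was compared with WT and with each other knockout. Levels are given as TMM-scaled CPM, mean ± SD over 2 libraries, and log2 changes as fitted values with their SE. A group with 0 counts in all its libraries gives a fold as a bound against a floor of 3 counts over the group, and a group with 1 to 3 counts gives a ratio with a 95% interval. Floors and intervals cover counting error only.

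Gene lists for chromatin, development, cell types, growth, metabolism, stress and signalling were written before the data were examined, as were the tests, the rule for named genes and the alternatives, except where an alternative is said to have been chosen later. Of 42 lists, 40 had at least 5 tested members, and the list of cancer-testis antigens (2 of 54 members tested) and that of the mitochondrial genome (0 of 13) were not tested. Lists were tested with camera in limma 3.58.1, two-sided, on the edgeR fit with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The estimated correlation was not always above the preset one. For mesenchymal genes it was -0.017 in both sgKDM5C and sgKDM6A. A call lost with an estimated correlation therefore need not reflect a higher correlation between members, and the cause of these losses was not tested. The p-values of each comparison were adjusted over the 40 lists, and a list was called at an adjusted p under 0.05. Members were also adjusted over the list alone. Lists share members, such as MYC, CCN1 and HOXA11, so calls of different lists are not independent. A list's median is given with genes at 0 counts set to their bound.

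The rule for named genes took the targeted genes in every sample. For each knockout against WT, it took the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM in the higher group, both knockout libraries on the same side of both WT libraries, and a symbol that is not clone-based or of a pseudogene. For each list it took up to 4 members with the smallest adjusted p. Among genes called in the same direction in all 3 knockouts, it took the 5 increases and 5 decreases whose smallest change was largest, and for each pair of knockouts, 3 genes in each direction. Genes of the Y chromosome and XIST were not named, and a few genes that the rule took are not reported here.

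Overlaps between knockouts were set beside the number expected for independent lists and beside 20 simulations of unchanged groups that shared simulated WT libraries, drawn with a spread pooled over the groups. The fit was tested on simulated data in which 200 genes were changed by known amounts among the 17527. At true log2 changes of 0.5, 1 and 2 it recovered 25.4%, 58.2% and 84.8% of the changed genes for sgKDM5C, 16.4%, 53.7% and 75.8% for sgKDM6A, and 22.4%, 65.7% and 84.8% for sgKMT2B. False calls were 11 of 123, 9 of 106 and 15 of 130.

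The alternatives were RLE and upper-quartile factors, no filter beyond 1 read over all libraries, a minimum mean CPM of 1, DESeq2 1.42.0, a fit of each pair of groups alone, the replicate number as a block, a minimum change of 2-fold, Spearman correlation and leaving out each library in turn. When a library is left out, the lone library of its group is assumed to vary like the other groups. Counts and list tests without the genes of shifted chromosomes, and fits with every library thinned to the total of WT replicate 2, were added after the data were seen. The counts without shifted chromosomes drop those genes from the calls of the main fit, with no new fit, so they are lower by construction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Splits of the samples into other groups were not counted, since each group has only 2 libraries.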

Results

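RNA was sequenced from HEK293T cells, a human embryonic kidney line, in 8 libraries of 4 groups with 2 libraries each. The first group was the unedited line (WT), and the other groups were knockout derivatives labelled sgKDM5C, sgKDM6A and sgKMT2B, in which a guide RNA was directed at the named gene. KDM5C removes methyl groups from H3K4, KDM6A removes them from H3K27, and KMT2B adds them to H3K4, so each comparison with WT asks which transcripts change when one of these chromatin enzymes is targeted. The total counts were 25099182 and 15868353 in WT replicates 1 and 2. They were 26701619 and 25062543 in sgKDM5C, 25331401 and 27591724 in sgKDM6A, and 25152073 and 25883185 in sgKMT2B. Between 22682 and 24385 genes had at least 1 count in a library. Replicates of a group correlated across genes at a Pearson r of 0.984 to 0.988 in log CPM (counts scaled to the TMM-adjusted library total). The labels do not say that replicates came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

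The 3 targeted genes were each lowest in their own knockout. KDM6A (ENSG00000147050, GRCh38 chromosome X, 44873177 to 45112602) was at 10.9 ± 0.845 CPM in sgKDM6A and 57.7 ± 4.93 CPM in WT (mean ± SD, n = 2), a fall of 5.19-fold (log2 change -2.39, SE 0.13, adjusted p = 9.38e-08). KMT2B (ENSG00000272333, chromosome 19, 35718019 to 35738878) was at 69.3 ± 8.86 CPM in sgKMT2B and 141 ± 6.25 CPM in WT (log2 change -1.03, SE 0.11, adjusted p = 2.44e-05). KDM5C (ENSG00000126012, chromosome X, 53191321 to 53225422) was at 321 ± 13.4 CPM in sgKDM5C and 456 ± 21.6 CPM in WT, a smaller fall of 1.41-fold (log2 change -0.50, SE 0.08, adjusted p = 0.00109). Single libraries gave 331 and 312 CPM of KDM5C in sgKDM5C against 440 and 471 CPM in WT. KDM5C was also lower than WT in sgKDM6A (log2 change -0.25, SE 0.08, adjusted p = 0.0359), and in sgKMT2B its change of -0.21 did not pass (adjusted p = 0.0667). In the direct comparisons KDM5C was lower in sgKDM5C than in sgKDM6A by 0.25 (SE 0.08, adjusted p = 0.0456) and than in sgKMT2B by 0.29 (SE 0.08, adjusted p = 0.0214), on the log2 scale. The position of each guide is not given in the sources used here, and the counts cover whole genes.

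**Figure D1:**
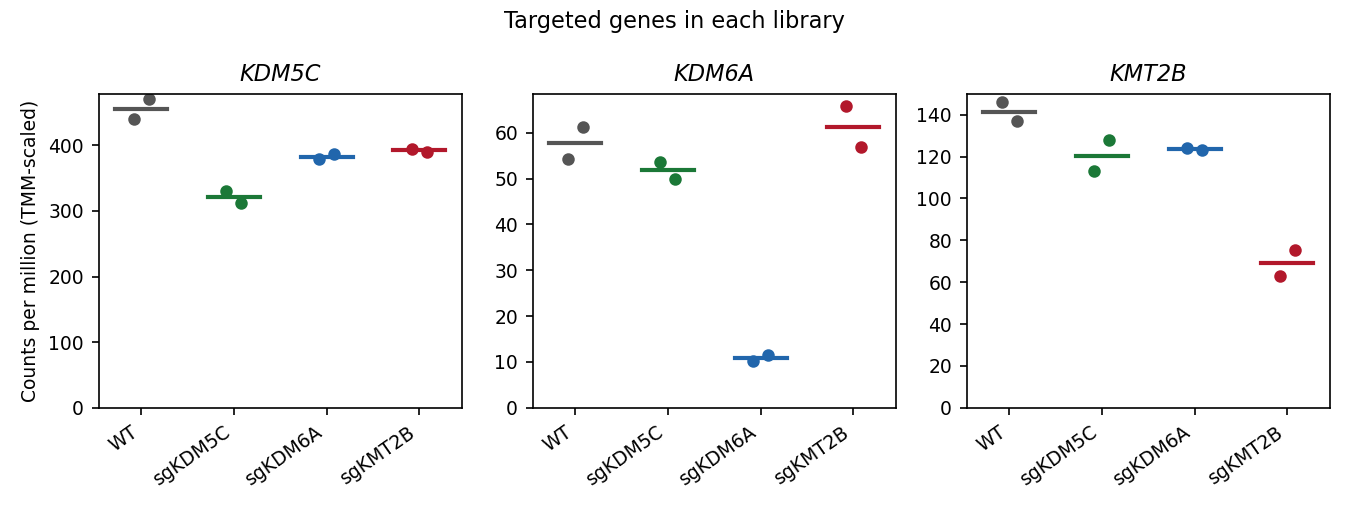
CPM (TMM-scaled, vertical axis, starting at 0) of KDM5C, KDM6A and KMT2B in each library of the 4 groups; points are single libraries and horizontal lines are group means of n = 2. KDM6A lies at 10.3 and 11.5 CPM in sgKDM6A against 54.2 and 61.2 CPM in WT, and the fall of KDM5C in sgKDM5C is the smallest of the 3.

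In sgKDM5C cells, 14 of 38 immediate early and MAPK genes, which respond early to growth signals and stress, 12 of 36 mesenchymal, 22 of 77 ribosomal protein and 10 of 25 cholesterol synthesis genes fell against WT (2, 5, 0 and 3 rose), while 12 of 38 HOX, 9 of 38 interferon-stimulated and 3 of 15 germline genes rose (2, 1 and 0 fell). Camera called each of these lists with a preset correlation, and each call was lost with an estimated one (adjusted p = 0.28 to 0.59 with an estimated correlation). The oncogene MYC fell from 481 ± 126 to 74.6 ± 0.245 CPM (log2 change -2.69, SE 0.16, adjusted p = 5.86e-07), and SNAI2, a transcription factor of the epithelial-mesenchymal transition, fell from 20.2 ± 4.49 to 0.875 ± 0.207 CPM (log2 change -4.51, SE 0.22, adjusted p = 3.07e-07). The meiotic cohesin subunit SMC1B rose from 0.127 ± 0.00429 to 5.46 ± 1.85 CPM (log2 change 5.38, SE 0.61, adjusted p = 0.000118). Of 17527 genes tested with edgeR's quasi-likelihood test, 3969 changed (22.6%), 1949 upward and 2020 downward. Of these, 727 rose and 366 fell by at least 2-fold. After SMC1B, the strongest increases under the rule for named genes were those of ZNF503-AS1 (4.92 ± 0.41, log2 change ± SE), WWC3 (3.35 ± 0.24), the chemokine receptor CCR10 (3.27 ± 0.28), the RNA methylation reader YTHDC1 (3.18 ± 0.84), the antiviral factor SAMD9 (3.13 ± 0.38), the complement component C5 (3.05 ± 0.40), the glutathione-degrading enzyme CHAC1 (2.88 ± 0.43), KHDC1-AS1 (2.82 ± 0.24) and the long non-coding RNA FENDRR (2.78 ± 0.31). Among the decreases, the neurofilament gene NEFM had 223 counts over both WT libraries and 0 in sgKDM5C, at least 101-fold lower. The others were the ribosomal protein gene RPS18 (-4.63 ± 0.80), the membrane metalloproteinase MMP16 (-4.35 ± 0.38), the stress-induced transcription factor ATF3 (-3.51 ± 0.31), the matrix glycoprotein SPARC (-3.00 ± 0.17), the small GTPase RHOB (-2.97 ± 0.45), LRATD2 (-2.84 ± 0.37) and EDIL3 (-2.81 ± 0.24). RPS18 shares sequence with near-identical copies and ZNF503-AS1 and KHDC1-AS1 lie antisense to other genes, so their values are uncertain. The count of changed genes was 2608 without WT replicate 2 and 1846 without sgKDM5C replicate 1, and YTHDC1 did not pass without the first (adjusted p = 0.117) or the second (adjusted p = 0.1).

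Of the 40 gene lists tested in sgKDM5C, 3 were called as higher and 8 as lower by camera with a preset correlation. With an estimated correlation camera called 0, 2 lists had an unadjusted p under 0.05, and fry called 11. HOX genes, which encode transcription factors that pattern the body axis, gave 12 of 38 members that rose, 2 that fell and 24 that did not pass; adjusted over the list alone, 17 rose and 3 fell. Their median log2 change was 0.47 (camera adjusted p = 0.0014, adjusted p = 0.48 with an estimated correlation). HOXB5 rose by 1.57 ± 0.16 and HOXB3 by 0.82 ± 0.13, whereas HOXA11 fell by 0.65 ± 0.11 and HOXD13 fell by 0.55 ± 0.10. Interferon-stimulated genes gave 9 of 38 members that rose and 1 that fell, with 28 not passing (11 and 1 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 0.014, adjusted p = 0.50 with an estimated correlation). Besides SAMD9, IFIT5 (1.03 ± 0.16), IFI35 (0.94 ± 0.19) and EPSTI1 (2.05 ± 0.43) rose. Of 15 germline and meiosis genes, SMC1B, the telomere-attachment factor MAJIN (2.37 ± 0.55) and the testis tubulin TUBA3D (2.54 ± 0.66) rose and 12 did not pass, the same 3 adjusted over the list alone; TUBA3D has near-identical copies and is uncertain. Their median was 0.51 (camera adjusted p = 0.041, adjusted p = 0.48 with an estimated correlation). Only 15 of the 49 listed germline genes passed the filter. SMC1B, at 5 counts over both WT libraries, could pass it only through a knockout group, which favours a rise. The germline call was lost without WT replicate 1 (adjusted p = 0.12), WT replicate 2 (0.061) or sgKDM5C replicate 2 (0.19), and with upper-quartile factors (0.058), no filter (0.053) or every library thinned to 1 depth (0.054). The interferon call was lost with a minimum mean CPM of 1 (adjusted p = 0.059), MAJIN did not pass without WT replicate 2 (0.0581) or sgKDM5C replicate 1 (0.0837), TUBA3D without WT replicate 1 (0.0965) and IFI35 without sgKDM5C replicate 1 (0.0606).

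The immediate early and MAPK list had the smallest camera p among the lists called as lower in sgKDM5C: 14 of 38 members fell, 2 rose and 22 did not pass (15 and 2 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 2.3e-07, adjusted p = 0.48 with an estimated correlation). Beside MYC and ATF3, the MAPK phosphatase DUSP1 fell by 2.56 ± 0.23 and the transcription factor KLF6 fell by 2.25 ± 0.22. Mesenchymal and EMT genes gave 12 of 36 members that fell and 5 that rose (15 and 6 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.0001, adjusted p = 0.28 with an estimated correlation). SNAI2, SPARC, the matricellular protein CCN1 (-2.45 ± 0.14) and the transcription factor TWIST1 (-1.16 ± 0.18) were among those that fell. In the collagen and extracellular matrix list 15 of 56 fell and 5 rose (18 and 7 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 0.015, adjusted p = 0.61 with an estimated correlation). Among those that fell were the protease ADAMTS1 (-1.50 ± 0.17), the protease inhibitor TIMP3 (-1.22 ± 0.14), the cartilage collagen COL2A1 (-3.99 ± 0.47) and the perlecan gene HSPG2 (-1.08 ± 0.13). The YAP target list gave 4 of 24 that fell and 2 that rose (5 and 2 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 0.046, adjusted p = 0.48 with an estimated correlation). CCN1, TEAD4 (-0.55 ± 0.11) and ANKRD1 (-1.36 ± 0.29) fell and AJUBA rose by 0.75 ± 0.13. The matrix call was lost without WT replicate 2 (adjusted p = 0.061) or sgKDM5C replicate 1 (0.089) and with fry (0.13), and the YAP call without WT replicate 2 (0.067), sgKDM5C replicate 1 (0.053) or sgKDM5C replicate 2 (0.088), with upper-quartile factors (0.058), no filter (0.061) or a minimum mean CPM of 1 (0.096). ANKRD1 did not pass without WT replicate 1 (adjusted p = 0.057) or sgKDM5C replicate 1 (0.0575).

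Growth and metabolism lists were also called as lower in sgKDM5C. Of 77 cytosolic ribosomal protein genes, 22 fell, 0 rose and 55 did not pass (26 and 0 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 1.4e-05, adjusted p = 0.59 with an estimated correlation). RPS7 fell by 0.63 ± 0.08, RPL36 fell by 0.58 ± 0.09 and RPL3 fell by 0.50 ± 0.08. In the MYC and ribosome biogenesis list 16 of 39 fell and 0 rose over all genes tested, against 17 and 4 adjusted over the list alone. Their median was -0.22 (camera adjusted p = 0.0001, adjusted p = 0.59 with an estimated correlation). MYC itself, the pyrimidine synthesis enzyme CAD (-0.77 ± 0.11), the nucleolar GTPase GNL3 (-0.72 ± 0.10) and WDR43 (-0.71 ± 0.11) led it. Cholesterol synthesis genes gave 10 of 25 that fell and 3 that rose, both over all genes and adjusted over the list alone. Their median was -0.22 (camera adjusted p = 4.7e-05, adjusted p = 0.48 with an estimated correlation). SQLE, the squalene epoxidase, fell by 1.31 ± 0.11, MSMO1 fell by 1.41 ± 0.14, DHCR7 fell by 0.83 ± 0.09 and the sterol sensor partner INSIG1 fell by 1.46 ± 0.17. The unfolded protein and heat shock list gave 13 of 33 that fell and 4 that rose (14 and 5 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 0.03, adjusted p = 0.50 with an estimated correlation). The endoplasmic reticulum chaperones HSPA5 (-1.13 ± 0.13) and PDIA6 (-0.68 ± 0.09) fell, whereas the cytosolic chaperones HSPB1 (1.07 ± 0.11) and DNAJA1 (1.08 ± 0.17) rose. The ribosomal protein and ribosome biogenesis calls were lost with fry (adjusted p = 0.078 for each), which does not compare a list with other genes. The unfolded protein call was lost without sgKDM5C replicate 2 (adjusted p = 0.19) and with a minimum mean CPM of 1 (0.059).

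In sgKDM6A cells, 31 of 56 extracellular matrix, 16 of 36 mesenchymal, 11 of 23 epithelial, 12 of 24 YAP target, 13 of 21 NOTCH, 6 of 10 pluripotency and 6 of 17 retinoic acid genes fell (0, 5, 1, 0, 1, 0 and 2 rose), while 9 of 15 clustered protocadherins and 16 of 38 HOX, 11 of 48 G2 and M phase and 14 of 39 ribosome biogenesis genes rose (0, 4, 1 and 3 fell). The calls of these lists by camera held with a preset correlation and were lost with an estimated one (adjusted p = 0.067 to 0.67 with an estimated correlation). SPARC went from 1258 counts over both WT libraries to 3 in sgKDM6A (ratio 564, 95% interval of counting error 192 to 2740; adjusted p = 1.1e-09). The epithelial keratin KRT8 fell from 60.6 ± 1.02 to 5.38 ± 0.323 CPM (log2 change -3.49, SE 0.11, adjusted p = 1.1e-09). Of 17527 genes tested, 4759 changed (27.2%), 2201 upward and 2558 downward. Of these, 577 rose and 825 fell by at least 2-fold. Strong increases under the rule included those of the neuronal adhesion protein SLITRK3 (5.42 ± 0.37), the glycosyltransferase B3GALT1 (5.28 ± 0.63), the p53-induced arrest factor RPRM (5.08 ± 0.31), the growth hormone receptor GHR (4.16 ± 0.33), the vesicle fusion protein VAMP7 (4.15 ± 0.43), the adhesion receptor ADGRL3 (4.03 ± 0.27), the monocarboxylate transporter SLC16A7 (3.97 ± 0.44), the heat shock protein HSPA1B (3.76 ± 0.93) and PLXDC2 (3.73 ± 0.28). Several decreases reached 0 counts in sgKDM6A: the cationic amino acid transporter SLC7A3 was at least 517-fold lower, the pseudouridine phosphatase PUDP at least 344-fold, the granzyme inhibitor SERPINB9 at least 149-fold and NEFM at least 99.9-fold. The peptide hormone gene ADM2 went from 336 to 3 counts (ratio 151, interval 51.1 to 734). SULT1A1, a sulfotransferase (-6.25 ± 0.25), DUSP8 (-5.28 ± 1.22), the glucose transporter SLC2A3 (-4.94 ± 0.24) and the teneurin TENM1 (-4.86 ± 0.42) fell too. HSPA1B, SULT1A1 and VAMP7 have near-identical or pseudoautosomal copies and are uncertain. The count of changed genes was 3141 without WT replicate 2 and 2483 without sgKDM6A replicate 1. HSPA1B rested on sgKDM6A replicate 2 (log2 change 0.55, adjusted p = 0.658 without it) and did not pass without WT replicate 1 (0.0608) or 2 (0.0664), and DUSP8 rested on WT replicate 1 (log2 change -0.77, adjusted p = 0.683 without it).

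By camera with a preset correlation, 4 of 40 lists were higher and 9 lower in sgKDM6A. An estimated correlation left 0, with 8 lists at an unadjusted p under 0.05, and fry called 20. The collagen and extracellular matrix list gave 31 of 56 members that fell, 0 that rose and 25 that did not pass (33 and 0 adjusted over the list alone). Their median was -0.70 (camera adjusted p = 2.1e-15, adjusted p = 0.22 with an estimated correlation). HSPG2 fell by 1.91 ± 0.13, the collagen gene COL6A2 fell by 1.25 ± 0.09, and the fibulins FBLN1 and FBLN2 fell by 1.19 ± 0.09 and 2.77 ± 0.23. COL6A2 lies on chromosome 21, whose genes with a mean of at least 5 CPM had a median change of -0.21 in sgKDM6A. Mesenchymal and EMT genes gave 16 of 36 that fell and 5 that rose (18 and 6 adjusted over the list alone). Their median was -0.54 (camera adjusted p = 3e-08, adjusted p = 0.067 with an estimated correlation). Leading those that fell were SPARC, CCN1 (-3.39 ± 0.14), its relative CCN2 (-2.64 ± 0.18) and the gelatinase MMP2 (-2.02 ± 0.17). Epithelial markers went the same way, 11 of 23 falling and 1 rising, with the same numbers adjusted over the list alone. Their median was -0.54 (camera adjusted p = 5.5e-06, adjusted p = 0.07 with an estimated correlation). After KRT8, these were KRT17 (-3.42 ± 0.42), the P-cadherin gene CDH3 (-2.01 ± 0.25) and the E-cadherin gene CDH1 (-1.86 ± 0.28). The YAP target list gave 12 of 24 that fell and 0 that rose (13 and 0 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 2.3e-07, adjusted p = 0.067 with an estimated correlation). ANKRD1 (-3.36 ± 0.34) and the RhoGAP DLC1 (-0.84 ± 0.11) fell beside CCN1 and CCN2. Fibroblast and endothelial markers gave 5 of 11 that fell and 0 that rose, also adjusted over the list alone. Their median was -1.17 (camera adjusted p = 0.01, adjusted p = 0.27 with an estimated correlation). Fibrillar collagen genes COL1A1 (-1.17 ± 0.13) and COL3A1 (-3.91 ± 0.48) fell, while LUM and PDGFRB were at 9 and 23 counts in WT and 0 and 3 in sgKDM6A. LUM did not pass without WT replicate 2 (adjusted p = 0.0526) or either sgKDM6A library (0.0736 and 0.07) or in a fit of the pair of groups alone (0.0557), nor PDGFRB without WT replicate 2 (0.0671) or sgKDM6A replicate 1 (0.119).

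Signalling and lineage lists called as lower in sgKDM6A were those of NOTCH, pluripotency, retinoic acid and glycolysis. NOTCH genes gave 13 of 21 that fell and 1 that rose, also adjusted over the list alone. Their median was -0.48 (camera adjusted p = 0.0003, adjusted p = 0.22 with an estimated correlation). The ligand JAG1 fell by 1.81 ± 0.15, HES4 fell by 0.70 ± 0.12 and the fringe enzyme RFNG fell by 0.68 ± 0.12, whereas the NOTCH antagonist NRARP rose by 0.64 ± 0.10 and lies on chromosome 9, whose median change was 0.28. Of 10 pluripotency genes 6 fell and 0 rose, also adjusted over the list alone. Their median was -0.62 (camera adjusted p = 0.00078, adjusted p = 0.22 with an estimated correlation). Among those that fell were UTF1 (-2.69 ± 0.19), TFCP2L1 (-1.75 ± 0.16), the telomerase subunit TERT (-0.57 ± 0.14) and KLF4 (-0.67 ± 0.20). The retinoic acid list gave 6 of 17 that fell and 2 that rose (7 and 2 adjusted over the list alone). Their median was -0.18 (camera adjusted p = 0.045, adjusted p = 0.36 with an estimated correlation). The retinol receptor STRA6 was at least 38.5-fold lower with 0 counts, the retinaldehyde dehydrogenase ALDH1A1 went from 75 counts to 1 (ratio 101, interval 17.5 to 4030), and CRABP2 (-1.27 ± 0.13) and RARB (-0.84 ± 0.19) fell. Both KLF4 and ALDH1A1 lie on chromosome 9 as well. Glycolysis and hypoxia genes gave 12 of 40 that fell and 4 that rose, also adjusted over the list alone. Their median was -0.11 (camera adjusted p = 0.045, adjusted p = 0.22 with an estimated correlation). SLC2A3, ENO2 (-1.01 ± 0.10) and BNIP3 (-0.74 ± 0.10) fell and the stress-induced mTOR inhibitor DDIT4 rose by 1.12 ± 0.16. The glycolysis call was lost without WT replicate 1 (adjusted p = 0.055), sgKDM6A replicate 1 (0.058) or 2 (0.079), with a minimum mean CPM of 1 (0.078), in a fit of the pair of groups alone (0.054) and without the genes of chromosomes 9, 18 and 21 (0.097). The retinoic acid call was lost without WT replicate 1 (0.089) or sgKDM6A replicate 2 (0.13), with no filter (0.06), a minimum mean CPM of 1 (0.16) or thinned libraries (0.063). TERT did not pass without sgKDM6A replicate 1 (0.0636), RARB without sgKDM6A replicate 2 (0.0666), nor KLF4 without WT replicate 2 (0.111) or sgKDM6A replicate 1 (0.15) or 2 (0.0569).

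Among the lists called as higher in sgKDM6A, the 15 tested clustered protocadherins, neuronal adhesion genes arrayed on chromosome 5, gave 9 that rose and 0 that fell, also adjusted over the list alone. Their median was 1.69 (camera adjusted p = 0.0005, adjusted p = 0.22 with an estimated correlation). Only 15 of the 52 listed members passed the filter. Members near 0 counts in WT could pass it only through a knockout group, which favours rises against WT. The named members were at low counts. PCDHB11 went from 1 to 67 (ratio 49.9, interval 8.65 to 2000), PCDHA10 from 0 to 38 (at least 9.42-fold higher) and PCDHB12 from 2 to 56 (ratio 20.8, interval 5.5 to 176), and PCDHB15 rose by 2.92 ± 0.74. These genes resemble each other and share exons, so counts of single members are uncertain. HOX genes gave 16 of 38 that rose and 4 that fell (17 and 4 adjusted over the list alone). Their median was 0.46 (camera adjusted p = 0.0069, adjusted p = 0.33 with an estimated correlation). HOXC9 (1.05 ± 0.16), HOXB5 (0.92 ± 0.16) and HOXB6 (0.71 ± 0.14) rose and HOXA11 fell by 0.70 ± 0.11. Genes of G2 and M phase gave 11 of 48 that rose and 1 that fell (10 and 1 adjusted over the list alone). Their median was 0.13 (camera adjusted p = 0.01, adjusted p = 0.25 with an estimated correlation). Those that rose included CENPF (1.29 ± 0.14), KIF14 (1.08 ± 0.19), CKAP2 (0.55 ± 0.10) and the spindle motor KIF11 (0.74 ± 0.14). In the MYC and ribosome biogenesis list 14 of 39 rose and 3 fell (17 and 3 adjusted over the list alone). Their median was 0.24 (camera adjusted p = 0.01, adjusted p = 0.67 with an estimated correlation). The nucleolar protein NOP58 (0.96 ± 0.15), the polyamine enzyme ODC1 (0.56 ± 0.09) and the RNA polymerase I factor UBTF (0.69 ± 0.12) rose, while MYC itself fell by 0.95 ± 0.15. The HOX call was lost without WT replicate 1 (adjusted p = 0.052), the G2 and M call without sgKDM6A replicate 2 (0.083) and the MYC call without WT replicate 2 (0.079) or sgKDM6A replicate 1 (0.062) and with fry (0.11). PCDHB12 did not pass without WT replicate 2 (0.05), nor PCDHB15 without WT replicate 1 (0.0774) or sgKDM6A replicate 1 (0.0623).

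In sgKMT2B cells, 22 of 35 genes of the list of p53 targets and cell cycle inhibitors rose and 1 fell. Of 39 genes of the amino acid response, 15 rose and 4 fell. In the same cells, 18 of 38 HOX, 19 of 47 neuronal, 10 of 20 kidney lineage, 5 of 10 pluripotency, 9 of 21 NOTCH and 18 of 38 immediate early genes fell (2, 4, 2, 1, 2 and 4 rose). Camera called these lists with a preset correlation, and 0 of the calls were kept with an estimated one (adjusted p = 0.079 to 0.55 with an estimated correlation). PHLDA3, a p53-induced inhibitor of AKT, rose from 21.6 ± 0.341 to 96.2 ± 1.38 CPM (log2 change 2.16, SE 0.11, adjusted p = 3.36e-08). Carbonic anhydrase CA2 fell from 175 ± 13.6 to 2.11 ± 0.197 CPM (log2 change -6.37, SE 0.15, adjusted p = 1.17e-11), and the kidney endocytic receptor LRP2 fell from 42.9 ± 2.18 to 1.85 ± 0.116 CPM (log2 change -4.53, SE 0.17, adjusted p = 3.22e-09). Of 17527 genes tested, 4931 changed (28.1%), 2398 upward and 2533 downward. Of these, 649 rose and 898 fell by at least 2-fold. The strongest increases under the rule were those of the chloride/proton exchanger CLCN4 (5.86 ± 0.53), SLITRK3 (4.95 ± 0.37), the fibrillar collagen COL3A1 (4.86 ± 0.24), CHAC1 (4.08 ± 0.43), the interferon-induced surface protein LY6E (3.83 ± 0.44), butyrylcholinesterase BCHE (3.69 ± 0.36), the innate immune sensor STING1 (3.54 ± 0.36), SAMD9 (3.44 ± 0.37), the synuclein SNCG (from 1 to 10.8 CPM) and the small RNA gene BCYRN1 (3.20 ± 0.98). CSTF2T, a polyadenylation factor, had 427 counts in WT and 0 in sgKMT2B, at least 181-fold lower, and NEFM went from 223 counts to 2 (ratio 142, interval 38.7 to 1180). Other decreases were those of TENM1 (-5.90 ± 0.48), MMP16 (-5.89 ± 0.46), the zinc finger factor INSM1 (-5.19 ± 0.29), the RNA helicase SKIC2 (-5.16 ± 1.46), the GDNF co-receptor GFRA1 (-4.87 ± 0.24) and the phosphatase subunit PPP2R2C (-4.71 ± 0.28). CSTF2T, GFRA1 and SNCG lie on chromosome 10, whose median change in sgKMT2B was -0.33, and INSM1 on chromosome 20, whose median was 0.30. BCYRN1 has near-identical copies and SKIC2 lies in the major histocompatibility region, which has alternate assemblies, so both are uncertain. The count of changed genes was 2339 without sgKMT2B replicate 1. BCYRN1 rested on sgKMT2B replicate 2 (log2 change 0.40, adjusted p = 0.784 without it) and did not pass without WT replicate 1 (0.152) or 2 (0.0943) or in DESeq2 (0.0556), and SKIC2 did not pass without WT replicate 1 (0.164) or sgKMT2B replicate 1 (0.0816) or 2 (0.112).

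In sgKMT2B, camera with a preset correlation called 4 of 40 lists as higher and 8 as lower, an estimated correlation left 0 (7 at an unadjusted p under 0.05), and fry called 25. Of 35 p53 targets and cell cycle inhibitors 22 rose, 1 fell and 12 did not pass (24 and 1 adjusted over the list alone). Their median was 0.59 (camera adjusted p = 1.1e-08, adjusted p = 0.079 with an estimated correlation). The p53 ubiquitin ligase gene MDM2 rose by 1.38 ± 0.10 and the stress sensor SESN2 by 1.57 ± 0.18, whereas the apoptosis gene PMAIP1 fell by 1.31 ± 0.14. The amino acid response list, targets of ATF4, gave 15 of 39 that rose and 4 that fell (20 and 4 adjusted over the list alone). Their median was 0.26 (camera adjusted p = 3.8e-05, adjusted p = 0.55 with an estimated correlation). NUPR1 (2.73 ± 0.26), CHAC1, SESN2 and the cystine transporter SLC7A11 (1.60 ± 0.20) rose. Clustered protocadherins gave 4 of 15 that rose and 0 that fell, also adjusted over the list alone. Their median was 1.42 (camera adjusted p = 0.0086, adjusted p = 0.31 with an estimated correlation). As in sgKDM6A, members near 0 counts in WT could pass the filter only through a knockout group, which favours rises. PCDHB11 went from 1 to 43 counts (ratio 33.9, interval 5.76 to 1370), PCDHB12 from 2 to 52 (ratio 20.5, interval 5.39 to 174), and PCDHGC3 (1.05 ± 0.28) and PCDHB15 (2.40 ± 0.76) rose. DNA methylation and repressor genes gave 9 of 27 that rose and 1 that fell, also adjusted over the list alone. Their median was 0.18 (camera adjusted p = 0.034, adjusted p = 0.25 with an estimated correlation). The silencing factors TASOR (0.76 ± 0.10), CBX5 (0.67 ± 0.12), MORC2 (0.58 ± 0.10) and HDAC2 (0.54 ± 0.11) were among them. This call was lost without sgKMT2B replicate 1 (adjusted p = 0.069) and with a minimum mean CPM of 1 (0.055), and the amino acid response call was lost with fry (0.082). PCDHB12 did not pass without sgKMT2B replicate 1 (0.0628), PCDHGC3 without WT replicate 2 (0.0819) or sgKMT2B replicate 1 (0.121), nor PCDHB15 without WT replicate 1 (0.167) or 2 (0.0601) or sgKMT2B replicate 1 (0.174).

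Of the developmental lists called as lower in sgKMT2B, HOX genes gave 18 of 38 that fell, 2 that rose and 18 that did not pass (20 and 2 adjusted over the list alone). Their median was -0.56 (camera adjusted p = 2.7e-09, adjusted p = 0.15 with an estimated correlation). HOXA11 (-1.82 ± 0.12), HOXB9 (-1.40 ± 0.09), HOXB6 (-1.91 ± 0.15) and HOXA6 (-1.91 ± 0.15) fell. Kidney lineage genes gave 10 of 20 that fell and 2 that rose, also adjusted over the list alone. Their median was -0.58 (camera adjusted p = 4.5e-06, adjusted p = 0.10 with an estimated correlation). Beside LRP2 and HOXA11, the podocyte sialomucin PODXL fell by 2.01 ± 0.13 and the GDNF receptor RET, on chromosome 10, fell by 1.68 ± 0.19. Neuronal and synaptic genes gave 19 of 47 that fell and 4 that rose (21 and 6 adjusted over the list alone). Their median was -0.48 (camera adjusted p = 0.00018, adjusted p = 0.14 with an estimated correlation). Among those that fell were NRXN3 (-4.00 ± 0.30), NRCAM (-2.09 ± 0.18) and CRMP1 (-2.00 ± 0.20). Of 10 pluripotency genes 5 fell and 1 rose, also adjusted over the list alone. Their median was -0.60 (camera adjusted p = 3.2e-05, adjusted p = 0.17 with an estimated correlation). UTF1, on chromosome 10, fell by 3.70 ± 0.21, TFCP2L1 fell by 2.48 ± 0.16, ESRRB fell by 3.42 ± 0.25, and KLF2 rose by 1.48 ± 0.23. NOTCH genes gave 9 of 21 that fell and 2 that rose (10 and 3 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 0.0033, adjusted p = 0.31 with an estimated correlation). Those that fell included the NOTCH effector HES1 (-2.03 ± 0.14), HES6 (-1.39 ± 0.12) and the ligands JAG2 (-1.13 ± 0.15) and DLL4 (-2.56 ± 0.36). The list of developmental transcription factors was not called by camera: 16 of 75 fell, 11 rose and 48 did not pass (16 and 12 adjusted over the list alone), with a median of -0.02 (adjusted p = 0.27), while fry called it as lower (adjusted p = 0.01). The pluripotency call was lost with no filter (adjusted p = 0.15), where the list's mean was 0.24.

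Immediate early and MAPK genes gave 18 of 38 that fell and 4 that rose in sgKMT2B (20 and 4 adjusted over the list alone). Their median was -0.77 (camera adjusted p = 3.2e-05, adjusted p = 0.31 with an estimated correlation). DUSP1 fell by 2.07 ± 0.22, MYC fell by 1.25 ± 0.15, ATF3 fell by 2.29 ± 0.29 and KLF6, on chromosome 10, fell by 1.80 ± 0.21. Cholesterol synthesis genes gave 10 of 25 that fell and 2 that rose, also adjusted over the list alone. Their median was -0.24 (camera adjusted p = 0.034, adjusted p = 0.55 with an estimated correlation). MSMO1 (-1.01 ± 0.13), INSIG1 (-1.26 ± 0.17) and FDFT1 (-0.58 ± 0.10) fell. Glycolysis and hypoxia genes gave 13 of 40 that fell and 4 that rose (13 and 5 adjusted over the list alone). Their median was -0.11 (camera adjusted p = 0.037, adjusted p = 0.25 with an estimated correlation). The neuronal enolase ENO2 fell by 1.57 ± 0.10, and HK1 (-0.97 ± 0.09), PFKFB3 (-0.85 ± 0.10) and PFKP (-0.79 ± 0.09), which also fell, all lie on chromosome 10. The glycolysis call was lost without the genes of chromosomes 10, 13 and 20 (adjusted p = 0.44), without sgKMT2B replicate 2 (0.081) or sgKDM6A replicate 1 (0.052) or 2 (0.051), with a minimum mean CPM of 1 (0.066) and in a fit of the pair of groups alone (0.068). The cholesterol call was lost without WT replicate 1 (adjusted p = 0.097) or sgKMT2B replicate 1 (0.058) and with a minimum mean CPM of 1 (0.066).

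**Figure D2:**
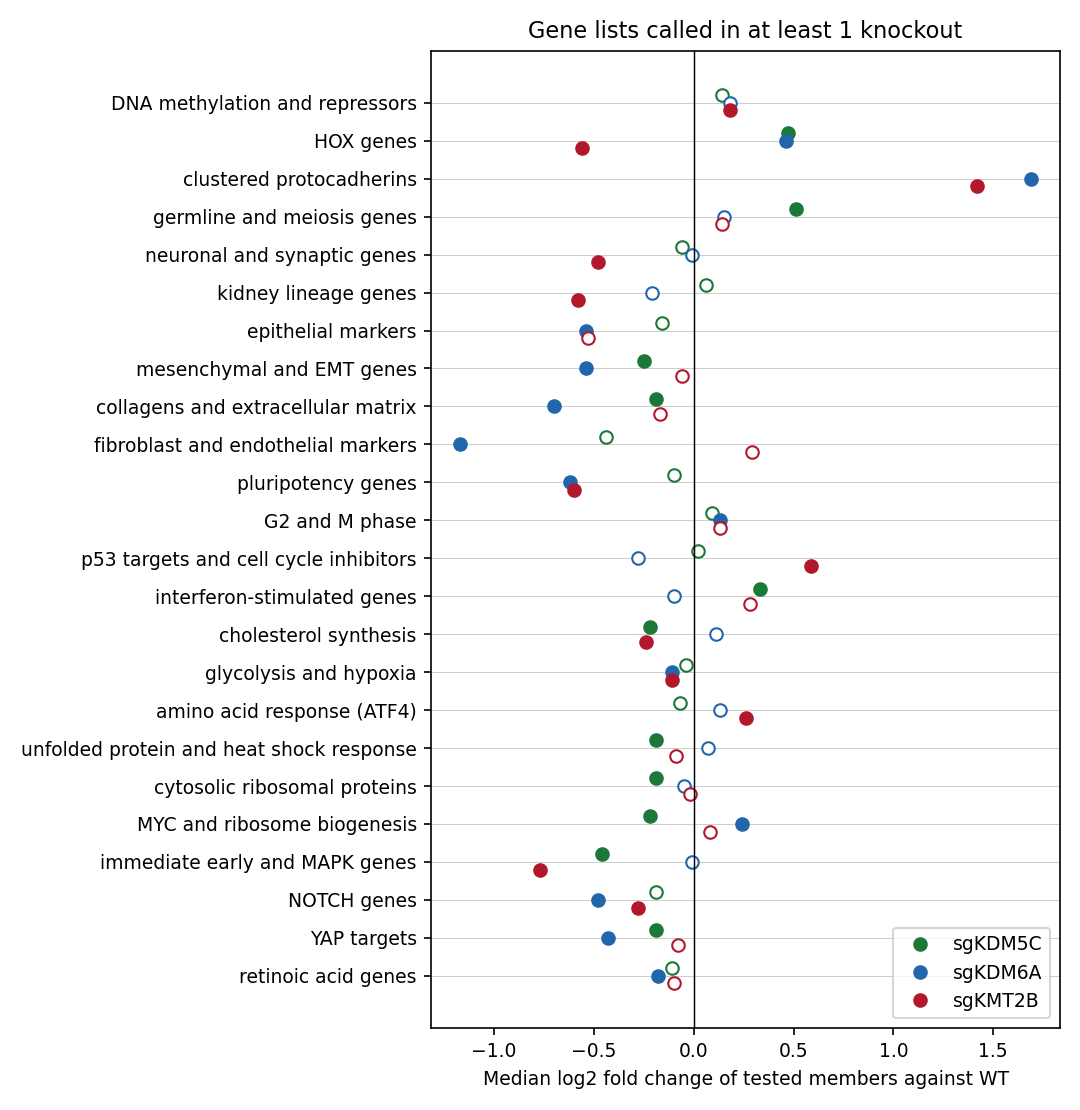
Median log2 fold change against WT (horizontal axis) of the tested members of each gene list that camera called in at least 1 knockout, with genes at 0 counts in a group set to their bound; filled points were called at an adjusted p under 0.05 with a preset correlation, open points were not, and no point is drawn for clustered protocadherins in sgKDM5C, where the median has no bound. HOX genes lie at 0.47 in sgKDM5C, 0.46 in sgKDM6A and -0.56 in sgKMT2B.

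The median change over a chromosome's genes was 0.2 or more in size on 3 chromosomes in sgKDM6A and on 3 others in sgKMT2B. These medians, and those of windows and parts of chromosomes, cover only tested genes with a mean of at least 5 CPM over all libraries. In sgKDM6A the median log2 change was 0.28 on chromosome 9 (469 genes), 0.25 on chromosome 18 (161 genes) and -0.21 on chromosome 21 (113 genes). In sgKMT2B it was -0.33 on chromosome 10 (470 genes), -0.39 on chromosome 13 (197 genes) and 0.30 on chromosome 20 (313 genes). On 3 of them the median was near 0 over part of the length, -0.08 before 69 Mb on chromosome 9, 0.01 before 32 Mb on chromosome 18 and 0.03 before 31 Mb on chromosome 20, boundaries chosen after seeing the data. That part of chromosome 9 was not uniform, as its windows of 25 genes lay at 0.39, -0.21, -0.09, -0.31 and -0.08. In sgKDM5C 0 chromosomes reached a median of 0.2 in size. Dropping the genes of the shifted chromosomes from the same calls, an alternative chosen after seeing the data and made with no new fit, left 4325 genes in sgKDM6A and 4355 in sgKMT2B.

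**Figure D3:**
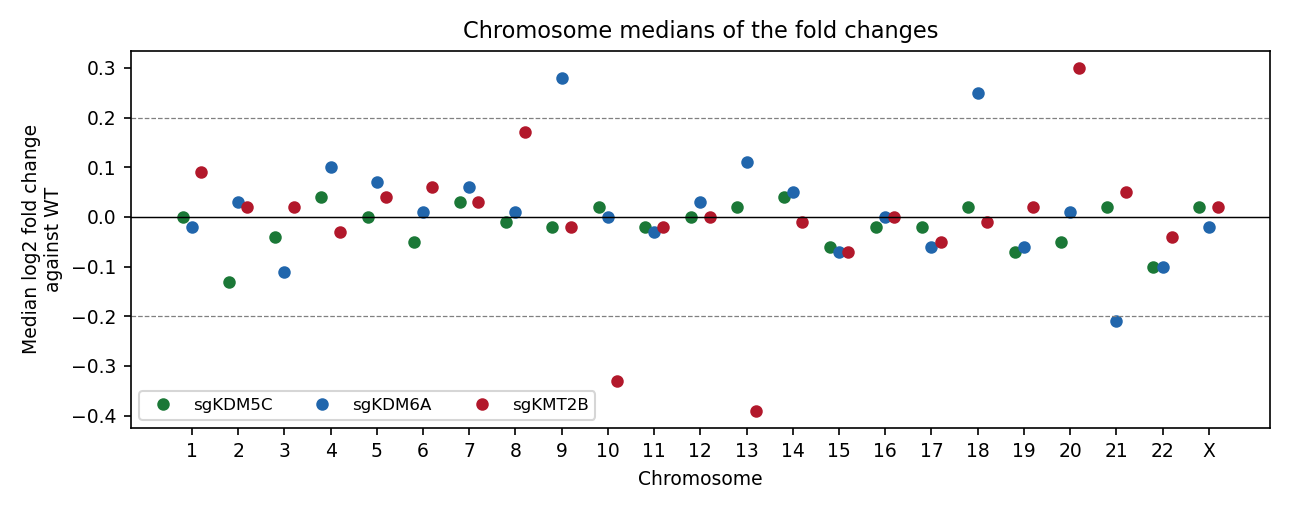
Median log2 fold change against WT (vertical axis) per chromosome (horizontal axis) in the 3 knockouts, over tested genes with a mean of at least 5 CPM. There is 1 point per knockout and chromosome, with dashed lines at 0.2 in size. Chromosomes 9, 18 and 21 in sgKDM6A and 10, 13 and 20 in sgKMT2B lie outside these lines.

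A set of genes went the same way in all 3 knockouts. The transcription factor subunit JUN fell from 2490 ± 106 CPM in WT to 440 ± 302 in sgKDM5C, 316 ± 103 in sgKDM6A and 407 ± 222 in sgKMT2B (adjusted p = 0.00118, 0.000254 and 0.000509), and RHOB fell from 2050 ± 362 to 262 ± 181, 148 ± 68.7 and 351 ± 184 CPM. The translation initiation factor EIF5 rose from 81.8 ± 15.6 CPM to 356 ± 29.4, 341 ± 10.2 and 367 ± 19.1 CPM (log2 changes 2.12, 2.06 and 2.16, SE 0.12 in each). Under the rule, SAMD9 (3.13, 3.48 and 3.44), CHAC1 (2.88, 2.61 and 4.08), the nuclear receptor coactivator NCOA5 (2.44, 2.48 and 3.06), EIF5 and ZNF780B (1.95, 2.32 and 2.07) led the shared increases, in the order sgKDM5C, sgKDM6A and sgKMT2B. NEFM, RHOB, JUN, CCN1 (-2.45, -3.39 and -2.75) and ATF3 (-3.51, -3.66 and -2.29) led the shared decreases. NCOA5 lies on chromosome 20, whose genes with a mean of at least 5 CPM had a median change of 0.30 in sgKMT2B. In all, 614 genes rose and 580 fell in all 3 comparisons. Independent lists of these sizes would share 33.5 and 42.6. Simulated unchanged groups against shared simulated WT libraries, with 1.3 calls per comparison, shared at most 1 gene in 20 simulations. So few simulated calls could share almost nothing, so this sets no chance level for the observed overlap. The total of 1194 was 611 without WT replicate 2, 624 without sgKDM5C replicate 1, 697 without sgKDM6A replicate 1 and 622 without sgKMT2B replicate 1. Without WT replicate 1 the total rose instead. The 3 comparisons share the WT libraries, which cannot be split with 2 libraries, so part of the excess may come from the shared controls.

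Between pairs of knockouts, sgKDM5C and sgKDM6A shared 897 genes that rose and 998 that fell (244.8 and 294.8 for independent lists; simulated mean 0.2). sgKDM5C and sgKMT2B shared 973 and 927 (266.7 and 291.9, simulated mean 0), and sgKDM6A and sgKMT2B shared 1033 and 1038 (301.1 and 369.7, simulated mean 0.1). The simulated means are near 0 because unchanged groups gave few calls, so they set no chance level for these counts. Genes that passed in opposite directions numbered 170, 194 and 271, below the 538.1, 558 and 668.1 of independent lists. The fold changes correlated across genes, which are not independent replicates, at r = 0.44, 0.41 and 0.38, against 0.56, 0.55 and 0.55 in simulated unchanged groups. Their covariances were 0.349, 0.309 and 0.324 against 0.107 in each simulation, differences of 0.242, 0.202 and 0.218. The correlations rose when either WT library was left out. They were 0.62, 0.61 and 0.57 without WT replicate 1, and 0.53, 0.52 and 0.46 without WT replicate 2. Each pair total also rose without WT replicate 1. As for all 3 knockouts, part of the excess may come from the shared WT libraries. The 3 pair totals of 1895, 1900 and 2071 were 1032, 1106 and 1161 without WT replicate 2. Without sgKDM5C replicate 1, its pairs with sgKDM6A and sgKMT2B shared 948 and 949. Without sgKDM6A replicate 1, its pairs with sgKDM5C and sgKMT2B shared 1086 and 1134. Without sgKMT2B replicate 1, its pairs with sgKDM5C and sgKDM6A shared 956 and 990.

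Comparisons of the knockouts with each other take no level from WT, but the WT libraries still enter the shared estimate of the spread. Camera with a preset correlation called 16, 14 and 16 of 40 lists in these comparisons, in the order given below. Only the list called in opposite directions against WT is described for each pair, and its direct test is no further support. Between sgKDM5C and sgKDM6A, 3468 of 17527 genes differed, 1915 higher and 1553 lower in sgKDM5C. SLC7A3 (1657 counts in sgKDM5C, 0 in sgKDM6A, at least 545-fold), PUDP (at least 308-fold) and SERPINB9 (at least 124-fold) were higher in sgKDM5C. ADGRL3 (-7.39 ± 0.36) and SLITRK3 (-6.62 ± 0.39) were lower, and the adhesion receptor ADGRB3 had 3 counts against 342 (ratio 115, interval 39.2 to 563). The MYC and ribosome biogenesis list gave 26 of 39 members lower in sgKDM5C and 0 higher (32 and 0 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 5.4e-12, adjusted p = 0.24 with an estimated correlation). The count was 1907 without sgKDM5C replicate 2, 1903 without sgKDM6A replicate 1 and 2079 without sgKDM6A replicate 2.

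Between sgKDM5C and sgKMT2B, 3882 genes differed, 2041 higher and 1841 lower in sgKDM5C. The chemokine gene CXCL12 had 406 counts in sgKDM5C and 0 in sgKMT2B (at least 126-fold), CSTF2T was at least 247-fold higher in sgKDM5C, and the basement membrane collagen COL4A4 had 310 counts against 2 (ratio 145, interval 39.7 to 1200). CXCL12 and CSTF2T lie on chromosome 10, whose median change in sgKMT2B against WT was -0.33. Higher in sgKMT2B were the cancer-testis gene SAGE1 (253 counts against 0, at least 90.4-fold), BCHE (log2 change -7.12 ± 0.48 in sgKDM5C against sgKMT2B) and SNAI2 (-6.55 ± 0.22), which was at 82.0 ± 5.34 CPM in sgKMT2B and 0.875 ± 0.207 CPM in sgKDM5C. HOX genes gave 28 of 38 members higher in sgKDM5C and 1 lower (30 and 1 adjusted over the list alone). Their median was 1.03 (camera adjusted p = 8.9e-22, adjusted p = 0.059 with an estimated correlation). The count was 2410 without sgKDM5C replicate 2, 2226 without sgKMT2B replicate 1 and 2215 without sgKMT2B replicate 2.

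Between sgKDM6A and sgKMT2B, 4356 genes differed, 2190 of them lower in sgKDM6A. CSTF2T was at least 187-fold higher and MMP16 higher by 6.69 ± 0.44 in sgKDM6A. SLC7A3 (at least 397-fold) and PUDP (at least 326-fold) were lower, and SPARC had 3 counts against 4871 in sgKMT2B (ratio 1720, interval 588 to 8340). With an estimated correlation camera called 1 list in this comparison (smallest adjusted p = 0.031), which was not that of HOX genes. HOX genes gave 27 of 38 higher in sgKDM6A and 1 lower (28 and 2 adjusted over the list alone). Their median was 0.93 (camera adjusted p = 1e-18, adjusted p = 0.068 with an estimated correlation). The count was 2810 without sgKMT2B replicate 1 and 2554 without sgKMT2B replicate 2.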

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

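The results here were picked out because a direct test between a pair of knockouts showed a difference between them, and the single genes named were chosen after their values were seen, for their opposite changes against WT. The lists were also chosen for calls in opposite directions against WT. Genes and lists called in opposite directions against WT differ directly almost by selection, so the direct comparison of these genes and lists is no further support.

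Between sgKDM5C and sgKDM6A, 170 genes were called in opposite directions against WT and also differed in the direct edgeR comparison, 101 higher in sgKDM5C and 69 higher in sgKDM6A. ADGRL3 was at 1.25 CPM in WT, 0.112 CPM in sgKDM5C and 19.5 CPM in sgKDM6A, and MAGEB2 at 4.04, 0.258 and 21.9 CPM. The list of MYC and ribosome biogenesis genes was lower in sgKDM5C than in sgKDM6A, with a mean log2 difference of -0.42, 26 members lower and 0 higher (32 and 0 adjusted over the list alone, camera adjusted p = 5.4e-12, adjusted p = 0.24 with an estimated correlation). Between sgKDM5C and sgKMT2B there were 194 such genes, 137 higher in sgKDM5C and 57 higher in sgKMT2B. BCHE was at 1.33 CPM in WT, 0.111 CPM in sgKDM5C and 16.2 CPM in sgKMT2B. HOX genes were higher in sgKDM5C than in sgKMT2B by a mean of 1.02, with 28 members higher and 1 lower (30 and 1 adjusted over the list alone, camera adjusted p = 8.9e-22, adjusted p = 0.059 with an estimated correlation). Between sgKDM6A and sgKMT2B there were 271 such genes, 122 higher in sgKDM6A and 149 higher in sgKMT2B. COL3A1 was at 1.51 CPM in WT, 0.0932 CPM in sgKDM6A and 43.2 CPM in sgKMT2B, and STING1 at 1.33, 0.119 and 15.7 CPM. HOX genes were higher in sgKDM6A than in sgKMT2B by a mean of 0.84, with 27 members higher and 1 lower (28 and 2 adjusted over the list alone, camera adjusted p = 1e-18, adjusted p = 0.068 with an estimated correlation).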

How the results depend on the processing

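The counts and list tests without shifted chromosomes and the fits with thinned libraries were chosen after the data were seen, and the other alternatives were planned. Of 19 main results, 277 alternative values stayed within their limits and 51 moved, and 0 changed direction. Of 223 called genes and list members that are named, 19 lost the call under some alternative, 17 of them only when a library was left out, and 0 reversed. Of 36 list calls against WT, 0 were kept with an estimated correlation, 19 stayed under every other alternative run on lists, fry included, and 17 were lost under at least 1 of those. DESeq2, the minimum change of 2-fold and Spearman correlation were not run on lists. A list with fewer than 5 tested members under an alternative gave no value there, and its call was counted as kept. With a minimum mean CPM of 1, 109 of 120 list results stayed the same and 8 weakened, so some were not tested there. RLE factors, DESeq2, a minimum mean CPM of 1, upper-quartile factors and fits of each pair of groups alone moved 0 of the main results for which they gave a value. The side with more calls changed in some: in sgKDM5C upper-quartile factors gave 2198 higher and 1797 lower (55% higher, against 49.1%) and no filter 2241 and 2099, in sgKMT2B no filter gave 2705 and 2520, and between sgKDM6A and sgKMT2B upper-quartile factors gave 2289 and 2061. Named genes under the minimum mean CPM of 1 were not tested in that fit and give no value there.

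With a minimum change of 2-fold, which removes calls by construction, 1093, 1402 and 1547 genes were called in sgKDM5C, sgKDM6A and sgKMT2B against WT, and 1117, 1397 and 1496 between sgKDM5C and sgKDM6A, sgKDM5C and sgKMT2B, and sgKDM6A and sgKMT2B. The shared counts of these pairs were then 381, 373 and 421, with 202 shared by all 3. Spearman correlations were 0.53 for sgKDM5C and sgKDM6A and 0.49 for sgKDM6A and sgKMT2B, and without a filter the Pearson correlations were 0.51 for sgKDM5C and sgKMT2B and 0.49 for sgKDM6A and sgKMT2B; the cause was not tested. With an estimated correlation, camera called 1 list between sgKDM6A and sgKMT2B (smallest adjusted p = 0.031) and 0 in each of the other direct comparisons. In the 3 knockouts against WT it called 0, 0 and 0 lists, while 2, 8 and 7 had an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 11, 20 and 25 lists were called, but 5 of the 36 calls by camera were lost: extracellular matrix (adjusted p = 0.13), ribosomal protein (0.078) and ribosome biogenesis genes (0.078) in sgKDM5C, ribosome biogenesis genes in sgKDM6A (0.11) and the amino acid response in sgKMT2B (0.082).

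Leaving out 1 library in turn leaves fewer samples, and the counts ran from 1846 to 3909 in sgKDM5C, 2483 to 4781 in sgKDM6A and 2339 to 4823 in sgKMT2B against WT. Between knockouts they ran from 1903 to 4077, 2215 to 4449 and 2554 to 4955. Shared counts ran from 948 to 2284, 949 to 2200 and 990 to 2398 for the pairs, and from 611 to 1593 for all 3. Correlations ran from 0.38 to 0.62, 0.34 to 0.61 and 0.32 to 0.57, and list calls from 8 to 13, 10 to 14 and 11 to 13. The targeted genes stayed called, KDM5C between -0.55 and -0.45, KDM6A between -2.48 and -2.31 and KMT2B between -1.17 and -0.90, with largest adjusted p of 0.0118, 4.58e-06 and 0.00119 in edgeR.

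Replicate numbers are shared between groups, but the labels tie them to no batch or day, and the deviations of same-numbered libraries correlated at only -0.02 to 0.18, so the numbers were not taken to pair the samples. As a hint from the data that they may not be arbitrary, replicate 2 lay above replicate 1 on principal component 2 (by 7.4 to 14.8) and below it on component 3 (-9.9 to -8.2) in all 4 groups. With the number as a replicate block, 4645, 5521 and 5576 genes were called against WT and 4110, 4415 and 4966 between knockouts, within 1.5 times the counts without it. The block ended 3 list calls, those of germline genes (adjusted p = 0.051) and of unfolded protein and heat shock genes (0.054) in sgKDM5C and of retinoic acid genes in sgKDM6A (0.054). With libraries thinned to 15868353 counts, 3794, 4559 and 4694 genes were called against WT, against 3969, 4759 and 4931 at full depth. Dropping the genes of shifted chromosomes from the main calls, with no new fit, left 4325 genes in sgKDM6A and 4355 in sgKMT2B. When the lists were tested again without these genes, 2 list calls were lost.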

Other observations

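The tests of shared chance values, of immediate early genes, of GC content, of neighbouring genes and of the X chromosome were chosen after the results were seen, as were the boundaries within chromosomes. The thinning test replaced an earlier test of depth, the count without WT replicate 2, before its own value was seen, and earlier tests of neighbouring genes, over all 7 lost genes and then over parts of them, were replaced by a count over all of them.

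The lists of H3K4 methyltransferase complexes, histone lysine demethylases and Polycomb complexes changed in single members without a call of the list by camera. Fry, however, called the H3K4 methyltransferase list as higher in sgKDM6A (adjusted p = 0.0099) and sgKMT2B (0.03). Camera did call the list of DNA methylation and repressor genes as higher in sgKMT2B, as described above. The targeted genes are members: KMT2B of the H3K4 methyltransferase list, and KDM5C and KDM6A of the demethylase list. The counts that fell therefore include KMT2B in sgKMT2B, KDM5C in sgKDM5C and sgKDM6A, and KDM6A in sgKDM6A. Of 22 tested genes of H3K4 methyltransferase complexes, 3 rose and 4 fell in sgKDM5C, 6 and 3 in sgKDM6A, and 6 and 2 in sgKMT2B (3 and 4, 7 and 3, and 6 and 2 adjusted over the list alone, camera adjusted p = 0.98, 0.12 and 0.31). KMT2E rose in all 3 knockouts (log2 changes 0.78, 0.76 and 0.85), and SETD1B rose in sgKDM6A (0.68) and sgKMT2B (0.83). Of 21 histone lysine demethylases, 3 rose and 4 fell in sgKDM5C, 4 and 4 in sgKDM6A, and 4 and 2 in sgKMT2B (4 and 6, 4 and 4, and 4 and 2 adjusted over the list alone, camera adjusted p = 0.44, 0.52 and 0.60). KDM4D rose in each (0.93, 1.13 and 1.20), and KDM6B, which like KDM6A removes methyl groups from H3K27, fell in sgKDM6A from 85.7 ± 1.64 to 43.3 ± 6.34 CPM (log2 change -0.98, SE 0.16, edgeR adjusted p = 0.00068). Polycomb genes gave 3 of 28 that rose and 6 that fell in sgKDM5C, 4 and 4 in sgKDM6A, and 7 and 3 in sgKMT2B (6 and 6, 6 and 5, and 8 and 5 adjusted over the list alone, camera adjusted p = 0.98, 1 and 0.52). PCGF1 fell in sgKDM5C (-1.08), RBBP7 fell in sgKDM6A (-0.86), and CBX8 (0.76) rose in sgKMT2B. Of 17 imprinted genes, 1 rose and 1 fell in sgKDM5C, 1 and 2 in sgKDM6A, and 7 and 2 in sgKMT2B, the same adjusted over the list alone (camera adjusted p = 0.98, 0.91 and 0.24). ZDBF2 rose in each (0.93, 0.86 and 0.70), and GRB10 rose in sgKMT2B (0.60).

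Markers of blood cells were not called by camera, while fry called them as higher in sgKDM5C (adjusted p = 0.021) and lower in sgKMT2B (0.034). Of 13 tested, 3 rose and 0 fell in sgKDM5C, 0 and 0 passed in sgKDM6A, and 0 rose and 1 fell in sgKMT2B (the same adjusted over the list alone, camera adjusted p = 0.49, 0.90 and 0.69). KRT8, which fell in sgKDM6A, rose in sgKMT2B from 60.6 ± 1.02 to 256 ± 12.1 CPM (log2 change 2.08, SE 0.10, edgeR adjusted p = 1.83e-08). In sgKMT2B the retinaldehyde dehydrogenase ALDH1A2 fell from 140 ± 14.2 to 19.3 ± 0.837 CPM (log2 change -2.86, SE 0.11, edgeR adjusted p = 3.22e-09), and in sgKDM6A the antiviral genes IFITM1 (-3.74) and BST2 (-4.13) fell.

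The first pattern is that 1194 genes were called in the same direction in all 3 knockouts. With every library thinned to the depth of WT replicate 2 the count was 1117, which argues against the difference in depth between libraries as the whole cause. Thinning leaves WT replicate 2 itself as it was, so it cannot show what the counting noise of that library adds. Leaving WT replicate 2 out altogether lowered the count, and leaving WT replicate 1 out raised it. Chance values shared through the WT libraries add the same covariance of fold changes with or without effects. The observed covariances of 0.309 to 0.349 exceeded the simulated mean of 0.107 (0.097 to 0.121 in 20 simulations) by at least 0.202. At the simulated spread this argues against chance values as the whole cause. That spread was pooled over the groups, while WT replicates differed most (chi-square per degree of freedom 16.91, against 8.21 to 11.12 in the knockouts). The simulated covariance may therefore be too low, and how many of the shared calls chance values add stays open. For an immediate early gene response in the WT libraries, 10 of 38 tested members of that list were lower in all 3 knockouts (26.3%, against 3.26% of other genes, Fisher's exact p = 3e-07), a small part of the 580 genes that fell, but in sgKDM6A the list was not called (13 fell and 6 rose, 13 and 7 adjusted over the list alone, median -0.01, camera adjusted p = 0.13), so it stays undecided. A state of the single set of WT libraries and an effect common to the knockouts stay open, because every comparison uses the same WT libraries.

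The second pattern is the median change of 0.2 or more in size on 6 chromosomes, 3 in sgKDM6A and 3 in sgKMT2B. It covers only tested genes with a mean of at least 5 CPM. After adjustment for a GC content trend, the smallest median on chromosomes 9 and 21 in sgKDM6A and 10, 13 and 20 in sgKMT2B was 0.2 in size, which argues against that trend there, but that of chromosome 18 was 0.15, below the 0.2 that defined a shift, and its shift cannot be told apart from a GC trend. For a difference in copy number, at least 68.3% of such a chromosome's genes lay on the side of its median in each library of the knockout, but the chromosomes were chosen for their medians, so this share decides nothing. In sgKDM6A the median was -0.08 before and 0.38 after 69 Mb on chromosome 9. Before 69 Mb the first 25 genes were at 0.39 and later windows of 25 genes between -0.31 and -0.08, so there was no clean step. On chromosome 18 it was 0.01 and 0.41 around 32 Mb. In sgKMT2B it was 0.03 and 0.40 around 31 Mb on chromosome 20. On chromosome 13 it was -0.54 and -0.27 around 50 Mb with no clean step, as windows of 25 genes after it lay at -0.19, -0.06 and -0.47 and the last 22 genes at 0. RNA counts do not measure copy number, and it cannot be told apart from a response of these regions to the knockouts.

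The third pattern is that 7 genes with a mean of at least 5 CPM in WT were at 3 counts or fewer in a knockout: SPARC, SERPINB9, PUDP, SLC7A3 and ADM2 in sgKDM6A, CSTF2T in sgKMT2B and NEFM in every knockout. Loss of a contiguous genomic segment stays open, as 2 of 9 losses, counted per knockout, had a nearest tested neighbour at 3 counts or fewer: STS, next to PUDP, went from 161 counts to 0 and DKK1, near CSTF2T, from 35 to 3 (ratio 14.8, interval 4.67 to 75.3). Other genes nearby had counts left: PRKG1, within which CSTF2T lies, went from 544 to 164 (log2 change -2.08), ASAH2B, which resembles ASAH2 and is uncertain, from 244 to 195 (-0.64), NEFL and STC1, on either side of NEFM, had log2 changes of -1.5, 0.38 and -1.07 and of 0.01, 0.04 and 2.3 in sgKDM5C, sgKDM6A and sgKMT2B, the other neighbour of PUDP, which has no symbol, was at -0.23, and the neighbours of SPARC, SERPINB9, SLC7A3 and ADM2 lay between -0.53 and 1.13. A single active copy on the X chromosome also stays open, as 2 of the 7 genes are X-linked (28.6%, against 3.5% of genes at that level, one-sided Fisher's exact p = 0.0225, but 0.191 without PUDP, which lies next to STS). Whether the knockouts are single clones, in which chance differences between cells would be fixed, is not given in the sources used here, and silencing through the targeted enzymes stays untested.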
